A study of Mus musculus with 17 samples.

How the data were processed

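RNA was measured by sequencing in 8 liver libraries, 4 WT and 4 SMSrKO, and in 9 libraries of hepatocytes isolated with collagenase, 3 WT, 3 dKO and 3 tKO. The groups were taken from the labels. The extract protocol on the labels names subcutaneous white adipose tissue (sWAT) for the SMSrKO experiment while the tissue label says liver, so the levels of adipocyte and hepatocyte genes were checked in every library.

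For liver, the authors gave whole-number counts per Ensembl gene, with chromosome, start, end, strand and length columns per the file headers. A TPM table was also deposited by the authors, and recomputing it from the counts and gene lengths gave each value within 5e-05. For hepatocytes, the deposited files held expected counts per Entrez gene and, per the file headers, transcript identifiers and gene lengths. The same deposited files gave FPKM values rounded to a lowest listed value of 0.01. Per the submitters' processing notes on the labels, Trimmomatic 0.36, STAR 2.5.2b, Bowtie2 2.2.5, DESeq2 1.30.1 and the genome builds GRCm38 and mm10 were used. Which tool served which experiment, the counting tools and the strand setting of the counts are not given in the sources used here, so overlapping and antisense genes are uncertain. Of the hepatocyte expected counts, 6.25% were not whole, and all were rounded to whole numbers before testing. The hepatocyte files list only genes above 0, and a gene missing from a file was given a count of 0 and is reported as not listed. Of 49315 liver genes, 49056 matched GENCODE release M21 by identifier, 44858 of them with the same start and end. Of 15632 hepatocyte genes listed in at least 1 file, 15611 matched RefSeq by Entrez identifier, and 12008 were listed in all 9 files.

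Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and DESeq2 1.42.0 served as an alternative. Genes were filtered with filterByExpr (minimum count 10), scaled by TMM, and tested with the robust quasi-likelihood F test. p-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05 and no fold minimum. Liver libraries formed 1 fit. All 9 hepatocyte libraries formed another, with a contrast for each pair of groups. Fold changes are on the log2 scale, and SE is the absolute fold change divided by the square root of F. CPM is the count relative to the TMM-scaled library total, given as mean ± SD over the libraries of a group. CPM summed over a gene list, family or pair is relative to the library total without TMM scaling. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

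Before the data were examined, 39 gene lists with 790 different symbols were fixed, of which 777 symbols were found in the liver files and 741 in the hepatocyte files. Lists with at least 3 measured genes were tested, 37 in liver and 34 in each hepatocyte contrast. They were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the lists of a contrast. The groups, contrasts, main tests, lists, most alternatives and the rule for named genes were also chosen before the data were examined. The rule took the 3 targeted genes, up to 10 higher and 10 lower genes with the largest fold among calls with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a predicted or clone name, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, it added the 5 with the smallest p. Genes named outside it are given as chosen after their values were seen. It was passed by 18 liver genes and by 4044, 4316 and 2735 genes for dKO against WT, tKO against WT and tKO against dKO. Chance gives groups that do not overlap in 10% of genes for 3 libraries against 3. Genes of families with near-identical copies are reported as uncertain.

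The tests were tried on simulated data. For SMSrKO against WT liver, with 15820 simulated genes, the test recovered 17.9% of 67 genes changed 1.5-fold, 67.2% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, and 5 of 126 calls were false. For dKO against WT hepatocytes, with 11471 simulated genes, it recovered 76.1%, 91.0% and 93.9% of 67, 67 and 66 genes, and 7 of 195 calls were false. A planted list had a camera adjusted p of 1.21e-22 in the first and 1.42e-23 in the second, and 0 of 33 random lists were called in either. Genes were simulated independently of each other, so these lists could not test whether the preset correlation suits the real data.

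Library depth was 24391627 to 47351126 counts in liver and 9221488 to 9665309 expected counts in hepatocytes. The 10 genes with the most counts held 14.7% to 17.0% of a liver library and 10.5% to 12.4% of a hepatocyte library. On principal component 1 of the liver libraries, with 28.5% of the variance, WT 1 lay at −48.7 against −9.1 to −15.3 for the other WT libraries. Component 1 of the hepatocyte libraries, with 62.9%, parted WT from the rest, and component 2, with 18.5%, parted dKO from tKO. The chi-square between counts of pairs of libraries of a group, over its degrees of freedom, was 1.56 to 2.76 in hepatocytes and 23.9 to 184.7 in liver.

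The alternatives were other scalings, count filters, DESeq2, limma-voom, limma on log2 TPM or FPKM with pseudocounts of 1 and 0.1, fits of only the 2 groups compared, and leaving out each library in turn. A fold change of at least 2 and the liver dispersion in the hepatocyte fit were added after the data were seen. The latter gave all genes 1 common dispersion and used edgeR's likelihood ratio test in place of the quasi-likelihood F test.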

Results

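RNA sequencing was carried out in mouse liver and in isolated mouse hepatocytes with lesions in genes of the sphingomyelin synthase family. The targeted genes were Samd8, which encodes SMSr, a ceramide phosphoethanolamine synthase of the endoplasmic reticulum, and Sgms1 and Sgms2, which encode the sphingomyelin synthases SMS1 and SMS2. The first experiment held 4 wild-type (WT) and 4 Samd8-knockout (SMSrKO) liver libraries from mice fed a high-fat diet with fructose for 16 weeks. The second held 3 WT, 3 Sgms1/Sgms2 double-knockout (dKO) and 3 Sgms1/Sgms2/Samd8 triple-knockout (tKO) hepatocyte libraries from mice of 2 months. Liver libraries held 24391627 to 47351126 gene counts and hepatocyte libraries 9221488 to 9665309 expected counts. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The common biological coefficient of variation was 20.3% in liver and 3.52% in hepatocytes.

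The RNA of the targeted genes was not lower in the libraries labelled as knockouts, with the exception of Sgms2 in hepatocytes. In liver, Samd8 (chromosome 14, 21750531 to 21798725, GRCm38) stood at 54.2 ± 3.67 CPM (SD, n = 4) in libraries labelled SMSrKO and 42.6 ± 6.38 (n = 4) in WT. Its log2 fold change was 0.35 ± 0.108 (SE), with an adjusted p of 0.218 in edgeR's quasi-likelihood test. In hepatocytes Samd8 stood at 69.7 ± 3.57 CPM in WT, 81.6 ± 6.01 in libraries labelled dKO and 101 ± 2.94 in those labelled tKO (n = 3 each). The tKO to WT difference was 0.53 ± 0.0575 (edgeR adjusted p = 5.41e-13). Sgms1 (chromosome 19, from 32122727) stood at 49.8 ± 3.34, 90.5 ± 5.55 and 58.7 ± 3.31 CPM in the same order, higher in dKO than in WT by 0.86 ± 0.0628 (edgeR adjusted p = 5.57e-21). Sgms2 (chromosome 3, from 131318985) stood at 183 ± 7.69, 150 ± 15.8 and 149.6 ± 7.12 CPM, lower in dKO than in WT by −0.29 ± 0.0521 (edgeR adjusted p = 6.22e-06). With the larger dispersion of the liver libraries, chosen after the data were seen, the calls of Samd8 in tKO and Sgms2 in dKO against WT ended (adjusted p = 0.189 and 0.759 in edgeR's likelihood ratio test). The counts cover whole genes, so a deletion of part of a gene, or of its protein product, would not show here. The groups are called by the names on the labels, which these levels did not check.

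**Figure D1:**
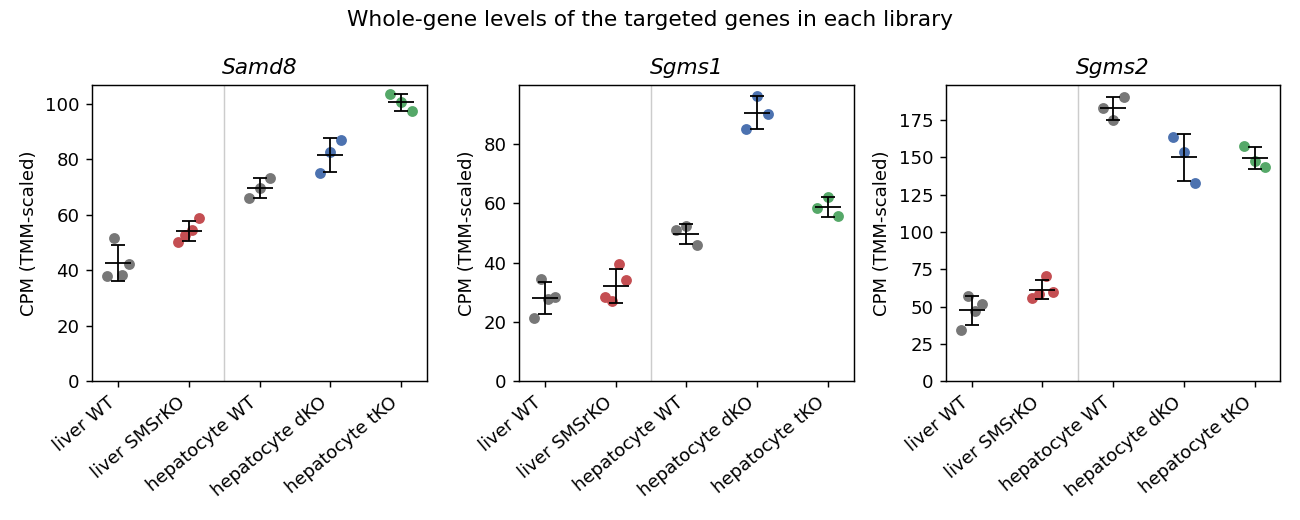
Each point is the TMM-scaled CPM of Samd8, Sgms1 or Sgms2 in 1 library, and bars give the mean and SD of the group (n = 4 in liver, n = 3 in hepatocytes). Samd8 lies at 50.4 to 59.0 CPM in libraries labelled SMSrKO and at 38.0 to 51.7 CPM in WT liver.

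Libraries named liver held the RNA of liver. Albumin (Alb) had 1068303 to 2199752 counts per library, while the adipocyte genes Adipoq and Lep had 0 to 3 and 0 counts. Of other adipocyte genes, Plin1 had 0 to 2 counts, Retn 0 to 14 and Cfd 9 to 63. The female-specific RNA Xist stood at 383.8 to 681.4 CPM in the liver libraries.

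The question in liver was what loss of SMSr changes in animals on the diet. The enzyme Agxt, which detoxifies glyoxylate in liver peroxisomes, rose by 1.12 ± 0.157 log2 in libraries labelled SMSrKO, from 134 ± 20.9 to 291 ± 53.9 CPM (edgeR adjusted p = 0.0216, n = 4 each). Smpd3, neutral sphingomyelinase 2, which releases ceramide from sphingomyelin, fell by 1.51 ± 0.197 log2, from 13.4 ± 3.45 to 4.73 ± 0.807 CPM (edgeR adjusted p = 0.0149). Other genes that rose were Trim80 (1.10 ± 0.179), the nucleotide sugar transporter Slc35d2 (0.90 ± 0.137), Fam13a (0.74 ± 0.118), the potassium channel Kcnn2 (0.61 ± 0.0793), the transcription factor Klf9 (0.55 ± 0.0873) and the corepressor Tle1 (0.48 ± 0.0652). Genes that fell were the apoptosis-enhancing nuclease Aen (−0.92 ± 0.123), Arhgap10 (−0.91 ± 0.147), Tbc1d31 (−0.89 ± 0.0937), Ttc38 (−0.87 ± 0.13), the fatty acid binding protein Fabp4 (−0.86 ± 0.136), the lysosomal sulfatase Arsb (−0.80 ± 0.104), the exocyst subunit Exoc4 (−0.76 ± 0.0961), Habp4 (−0.61 ± 0.0957) and the signalling adaptor Traf3 (−0.56 ± 0.0737). The pseudogene Rpl3-ps1 rose by 3.33 ± 0.179 log2 (edgeR adjusted p = 6.32e-05), a value left uncertain because it shares sequence with Rpl3.

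Genes below 5 CPM were chosen after their values were seen. Grem1, a secreted antagonist of BMP, had 762 counts in the 4 SMSrKO libraries and 1 in the 4 WT libraries. Phyhip rose by 5.44 ± 0.681 log2 (7.07 without WT 2) and Krt5, a basal keratin, by 1.64 ± 0.268, while Eps8l1 fell by 3.34 ± 0.206 and the adenylyl cyclase Adcy1 by 2.74 ± 0.281. In all, edgeR called 37 of 15820 genes, 19 higher and 18 lower in libraries labelled SMSrKO, and 21 of them changed at least 2-fold. At an unadjusted p under 0.05 the count was 2075. DESeq2 called 451 genes, and scaling by library totals alone gave 39 calls with 38.5% higher instead of 51.4%. Without WT 1, which lay apart from the other libraries, 109 genes were called, 42 higher and 67 lower, including 35 of the 37, while without WT 3, WT 4, SMSrKO 5 or SMSrKO 7 the count was 23, 11, 13 or 15. Of the 23 called genes named here, Rpl3-ps1, Tbc1d31, Grem1, Eps8l1 and Adcy1 kept the call without any single library, and the other 18 lost it without at least 1 library, at edgeR adjusted p of up to 0.172, with their direction kept.

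**Figure D2:**
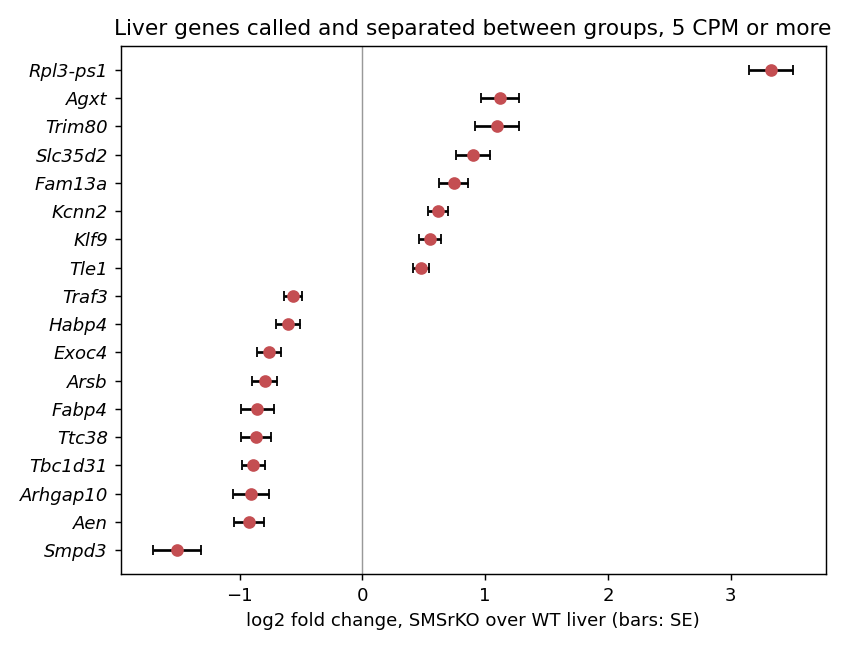
Points give the log2 fold change of libraries labelled SMSrKO over WT liver and bars its SE, for the 8 higher and 10 lower genes that passed the naming rule. Rpl3-ps1 lies at 3.33 and Smpd3 at −1.51.

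Targets of p53, the regulator of cell cycle arrest and apoptosis, stood lower in libraries labelled SMSrKO. Of 20 measured members 0 passed edgeR over all genes, and 8 lower and 1 higher passed adjusted over the list alone (camera adjusted p = 4.24e-09; adjusted p = 0.127 with an estimated correlation; fry adjusted p = 0.0301). Among them Cdkn1a stood at −1.87 ± 0.327 log2, Zmat3 at −0.79 ± 0.137 and Ccng1 at −0.55 ± 0.114, with edgeR adjusted p of 0.068, 0.0574 and 0.0964 over all genes. Without WT 1, 4 p53 targets of the 20 were called lower over all genes (camera adjusted p = 5.42e-11; adjusted p = 0.0386 with an estimated correlation). Of 20 de novo lipogenesis genes, 0 passed over all genes and 3 lower adjusted over the list alone, with a median of −0.55, or −0.35 without WT 1 (camera adjusted p = 2.02e-05; adjusted p = 0.415 with an estimated correlation). Of 24 genes of xenobiotic metabolism, 0 passed over all genes and 5 higher adjusted over the list alone (camera adjusted p = 0.000532; adjusted p = 0.415 with an estimated correlation). Of 20 lipoprotein genes, 0 passed over all genes and 4 higher, Lcat, Apoc4, Apoh and Apoa5, adjusted over the list alone (camera adjusted p = 1.33e-05; adjusted p = 0.415 with an estimated correlation). Of 21 genes of sphingolipid breakdown, Smpd3 alone passed, both over all genes and adjusted over the list alone (camera adjusted p = 0.0446; adjusted p = 0.415 with an estimated correlation). The camera call of that list was lost without WT 3, WT 4, SMSrKO 5, SMSrKO 6 or SMSrKO 7. Of 19 genes of sphingolipid synthesis, 0 passed over all genes and 1 lower, Sptlc2, adjusted over the list alone (camera adjusted p = 0.65). Hepatocyte identity genes stood higher as a list (median 0.26, camera adjusted p = 9.67e-05), and macrophage and inflammatory genes lower (medians −0.34 and −0.45, camera adjusted p = 0.000193 and 0.00038). In these 3 lists 0 genes passed over all genes or adjusted over the list alone, and adjusted p was 0.415, 0.415 and 0.416 with an estimated correlation. Immediate early genes, which handling of tissue also induces, numbered 0 of 26 over all genes and 5 lower adjusted over the list alone (median −0.40, camera adjusted p = 0.00556; adjusted p = 0.415 with an estimated correlation, and no camera call without WT 3 or SMSrKO 6). Stress response genes numbered 0 of 27, and 1 higher and 3 lower adjusted over the list alone (median −0.30, or −0.13 without WT 1, camera adjusted p = 0.00142; adjusted p = 0.415 with an estimated correlation). Circadian clock genes, which follow the time of day, numbered 0 of 18, and 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0825). Erythroid genes stood lower, with 0 of 7 over all genes and 5 adjusted over the list alone (median −1.68, camera adjusted p = 2.3e-07; adjusted p = 0.415 with an estimated correlation). The 22 acute phase genes had a median of −0.47 with all libraries and −0.12 without WT 1, whose summed acute phase level was 54610 CPM against 22210 to 27080 in the other WT libraries. The camera test with preset correlation called 24 of 37 measured lists, 0 of them with an estimated correlation, and fry called 1, the p53 targets. Without WT 1 camera called 25, 1 of them with an estimated correlation, and fry called 7. At an unadjusted p under 0.05 in edgeR, 10 p53 targets were lower and 1 higher, 10 de novo lipogenesis genes and 5 erythroid genes were lower, and 7 lipoprotein and 7 xenobiotic genes were higher.

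In hepatocytes, the comparison of dKO with WT addressed loss of both sphingomyelin synthases. Interferon-induced genes, inflammatory mediators and markers of endothelial, macrophage and stellate cells rose in libraries labelled dKO, while most male-biased genes fell. Counts of list members were the same over all genes and adjusted over the list alone, except where both are given. All 29 measured interferon response genes rose, with a median log2 fold change of 1.5 (camera adjusted p = 3.99e-71). Gbp2 rose by 2.36 ± 0.0606, Gbp3 by 2.15 ± 0.0558, Isg15 by 1.80 ± 0.0537 and the transcription factor Irf7 by 1.54 ± 0.0492 (edgeR adjusted p = 3.84e-50 to 1.77e-43, n = 3 each). Of 18 inflammatory genes 17 rose (median 2.0, camera adjusted p = 2.32e-49). The chemokines Ccl2, Cxcl2 and Cxcl1 rose by 2.97 ± 0.0545, 2.60 ± 0.0792 and 1.69 ± 0.0542, and the interleukin 1 receptor antagonist Il1rn by 2.72 ± 0.0527. Other genes that rose were the matrix metalloprotease Mmp3 (6.17 ± 0.352), the inducible nitric oxide synthase Nos2 (6.06 ± 0.196), the proteoglycan Dcn (6.02 ± 0.204), the phagocyte oxidase subunit Cybb (5.30 ± 0.337), the oxidase Duox2 (5.28 ± 0.202) and its maturation factor Duoxa2 (5.02 ± 0.243), Cib3 (5.07 ± 0.265), Krt23 (5.03 ± 0.323) and thrombomodulin Thbd (4.99 ± 0.192). Each averaged below 1 CPM in WT libraries, and leaving out WT 3 moved Mmp3 to 7.39 and Krt23 to 5.62, and leaving out WT 1 moved Cybb to 6.23 and Duoxa2 to 5.79.

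Markers of other cell types moved with these genes. All 17 liver endothelium genes rose (median 2.65, camera adjusted p = 7.26e-18), among them Cdh5 (3.20 ± 0.101) and Pecam1 (3.21 ± 0.133). The 11 macrophage genes all rose (median 2.23, camera adjusted p = 5.44e-11), with Mpeg1 at 2.12 ± 0.0706. Of 15 stellate cell and fibrosis genes, 13 rose (median 2.14, camera adjusted p = 4.3e-10), with Col4a1 at 1.68 ± 0.0717. That median was 2.13 to 3.37 without single libraries, and 3.10 to 3.37 without WT 1, WT 2, WT 3, dKO 6, tKO 7 or tKO 9. Acute phase genes, which hepatocytes express in inflammation, numbered 15 higher and 4 lower of 22 over all genes, and 15 and 6 adjusted over the list alone (camera adjusted p = 9.01e-25). Lcn2 rose by 2.13 ± 0.0369, Crp by 1.70 ± 0.0399 and Saa2 by 1.58 ± 0.0381. Immediate early genes, which cell isolation also induces, numbered 21 higher and 2 lower of 26 (camera adjusted p = 3.5e-12), with Fos at 2.25 ± 0.112.

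Of 20 male-biased genes 14 fell and 2 rose (median −1.20, camera adjusted p = 1.67e-21). Serpina1e, Mup11, Mup7, Mup15, Mup16, Mup12 and Mup3 stood at −4.07 ± 0.0524, −3.71 ± 0.0612, −2.99 ± 0.17, −2.63 ± 0.0447, −2.45 ± 0.104, −2.26 ± 0.296 and −1.97 ± 0.0379, while Mup20 rose by 2.36 ± 0.0553, values left uncertain because these families hold near-identical copies. Sult5a1 fell by 2.79 ± 0.209 and Serpina12 by 2.21 ± 0.168. Of 20 de novo lipogenesis genes 11 fell and 4 rose over all genes, and 12 and 4 adjusted over the list alone (camera adjusted p = 0.00054; adjusted p = 0.0999 with an estimated correlation). Elovl6 fell by 1.20 ± 0.067, the acetyl-CoA carboxylase Acaca by 1.03 ± 0.0531 and the desaturase Scd1 by 0.86 ± 0.0433. The chaperones Hspa5 and Hsp90b1 fell by 0.70 ± 0.0344 and 0.71 ± 0.0349, in a list with 10 members higher and 12 lower of 27 (camera adjusted p = 0.0196; adjusted p = 0.136 with an estimated correlation). Sphingolipid synthesis genes numbered 6 higher and 3 lower of 17 (camera adjusted p = 0.458), with the ceramide kinase Cerk at 1.31 ± 0.153 and Sptlc2 at 0.42 ± 0.0493.

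In all, edgeR called 5045 of 11471 genes between dKO and WT, 2749 higher and 2296 lower, of which 849 changed at least 2-fold, 734 of them higher. A setting chosen after the data were seen gave all genes the common dispersion of the liver libraries, larger than that of the hepatocytes. It used edgeR's likelihood ratio test. With this liver dispersion 1055 genes were called, including 23 of the 29 interferon genes, 17 of the 17 endothelial genes and 12 of the male-biased genes lower. Of the 1055 calls 82.4% were higher instead of 54.5%. Of the acute phase genes 7 higher and 0 lower were called, of de novo lipogenesis 1 and 3, of immediate early genes 13 and 0, of the stress response 3 and 5 and of sphingolipid synthesis 1 and 0. camera called 16 of 34 lists, 8 of them with an estimated correlation.

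The comparison of tKO with WT addressed loss of all 3 enzymes. Libraries labelled tKO shared the rise of interferon and inflammatory genes, and most female-biased genes fell. Member counts were again the same over all genes and adjusted over the list alone, except where both are given. All 29 interferon genes rose (median 1.42, camera adjusted p = 3.01e-77), with Oasl2 at 2.57 ± 0.0724. All 18 inflammatory genes rose (median 1.81, camera adjusted p = 1.08e-34), with Ccl2 at 2.70 ± 0.055. Of 21 female-biased genes 18 fell and 2 rose (median −1.77, camera adjusted p = 4.33e-27), against 10 and 7 in dKO (median −0.27, camera adjusted p = 0.000406; adjusted p = 0.128 with an estimated correlation). The cytochrome Cyp2b9 fell from 146 ± 5.02 to 0.171 ± 0.0582 CPM, Cyp3a41a by 1.74 ± 0.0462 log2 and Cyp2c69 by 1.65 ± 0.0424, near its fall of 1.56 ± 0.0423 in dKO (n = 3 each). Cyp2b13 and Sult2a2, at 43.4 ± 0.707 and 9.13 ± 1.12 CPM in WT, were not listed in the tKO files. These genes belong to families of similar sequence, so single values are uncertain. Of 20 male-biased genes 13 fell and 3 rose (median −0.89, camera adjusted p = 2.4e-06), and Mup20 rose by 4.69 ± 0.0518.

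Other genes that rose in libraries labelled tKO were Cib3 (6.59 ± 0.209), Cybb (5.84 ± 0.309), Nos2 (5.80 ± 0.204), Duox2 (5.41 ± 0.197), the lipoprotein lipase Lpl (5.29 ± 0.212), Dcn (5.11 ± 0.232), Duoxa2 (4.95 ± 0.244) and Krt23 (4.93 ± 0.327), with Cybb at 6.77 and Duoxa2 at 5.73 without WT 1 and Krt23 at 5.52 without WT 3. Those that fell were Sult5a1 (−3.89 ± 0.242), Cyp3a44 (−3.76 ± 0.147), the xenobiotic-induced cytochrome Cyp2b10 (from 113 to 14.1 CPM), Mup15, Mup17 and Mup11. All 11 macrophage genes and 16 of 17 endothelial genes rose over all genes, and 11 and 17 adjusted over the list alone (camera adjusted p = 1.22e-10 and 2.4e-06). Of 15 stellate cell genes 12 rose and 1 fell over all genes, and 12 and 2 adjusted over the list alone (camera adjusted p = 0.00177; adjusted p = 0.198 with an estimated correlation). Acute phase genes numbered 11 higher and 10 lower of 22 (camera adjusted p = 0.162). Lcn2 rose by 1.64 ± 0.0366 and Crp by 1.45 ± 0.0399, while the fibrinogen chains Fga and Fgg fell by 0.88 ± 0.0328 and 0.90 ± 0.0338. Of 26 immediate early genes 24 rose and 1 fell (camera adjusted p = 1.6e-12). Of 24 hepatocyte identity genes 14 fell and 3 rose (camera adjusted p = 8.46e-05; adjusted p = 0.379 with an estimated correlation), with Alb at −0.37 ± 0.0299 and transferrin, Trf, at −0.69 ± 0.0312.

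The edgeR test called 5435 of 11471 genes between tKO and WT, 2935 higher and 2500 lower, and 897 changed at least 2-fold. With the liver dispersion 1221 were called, including 25 of the 29 interferon genes and 15 female-biased genes lower, and 71.8% were higher instead of 54.0%. Of the hepatocyte identity genes 0 higher and 2 lower were called, of the acute phase genes 5 and 5, and of immediate early genes 13 and 0. Scaling by library totals alone gave 60% of calls higher. camera called 12 of 34 lists, 7 of them with an estimated correlation.

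By the labels, the comparison of tKO with dKO addressed what loss of SMSr adds where SMS1 and SMS2 are already missing. RNA of Sgms1 also differed between these groups, at −0.625 ± 0.0608 log2, and Samd8 stood at 0.303 ± 0.0561 (edgeR adjusted p = 1.7e-14 and 9.23e-06). Both calls ended with the liver dispersion. The calls of this comparison can therefore not be assigned to Samd8 alone. Acute phase genes fell in libraries labelled tKO, all 22 of them (median −0.45, camera adjusted p = 1.09e-34). Where only 1 count of list members is given, it was the same over all genes and adjusted over the list alone. Serpina3n fell by 0.84 ± 0.0351, Saa2 by 0.75 ± 0.0366 and Steap4 by 0.54 ± 0.0369. Female-biased genes numbered 13 lower and 2 higher of 21 over all genes, and 13 and 3 adjusted over the list alone (median −1.73, camera adjusted p = 4.55e-29). Cyp2b9 fell from 114 ± 3.73 to 0.171 ± 0.0582 CPM, Cyp3a41a by 2.36 ± 0.0454 log2 and Cyp3a44 by 2.38 ± 0.176, while Cyp2a4 rose by 0.89 ± 0.0366. Cyp2b13 and Sult2a2 stood at 49.5 ± 2.99 and 17.9 ± 0.195 CPM in dKO and were not listed in tKO. Genes of the endoplasmic reticulum stress response numbered 17 higher and 4 lower of 27 (median 0.30, camera adjusted p = 3.42e-13). The chaperones Hspa5, Hsp90b1 and Creld2 rose by 0.60 ± 0.0343, 0.66 ± 0.0349 and 1.11 ± 0.0613. Their levels were 3377 to 3585, 1791 to 1846 and 86.79 to 99.23 CPM in WT. Levels in dKO lay below these, at 2101 to 2209, 1098 to 1132 and 45.94 to 49.01. Levels in tKO lay near WT, at 3123 to 3401, 1688 to 1833 and 98.54 to 111.8. At an unadjusted p under 0.05 in edgeR, 14 of the 27 stress response genes were higher and 6 lower in tKO than in WT. Targets of the transcription factor NRF2, which responds to oxidants, numbered 12 higher and 2 lower of 19 (median 0.42, camera adjusted p = 2.17e-12), with the glutathione transferases Gstm3 and Gsta2 at 1.71 ± 0.0596 and 0.76 ± 0.061.

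Of 20 male-biased genes 10 rose and 2 fell (median 0.35, camera adjusted p = 3.57e-12), with Mup20 at 2.33 ± 0.0421 and Cyp2d9 at 1.39 ± 0.112. Cyp2d9 stood at 20.06 to 21.84 CPM in WT, 8.195 to 9.824 in dKO and 21.95 to 24.81 in tKO. Endothelial genes fell, 13 of 17 with 0 higher (median −0.74, camera adjusted p = 1.54e-06), with Cdh5 at −0.86 ± 0.0734. Of 15 stellate cell genes 11 fell (camera adjusted p = 0.000146; adjusted p = 0.104 with an estimated correlation), and of 11 macrophage genes 3 rose and 3 fell over all genes, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.567). De novo lipogenesis genes went both ways, 6 higher and 6 lower of 20, with a median of −0.05 against camera's upward direction (camera adjusted p = 0.0309; adjusted p = 0.274 with an estimated correlation, and no camera call without dKO 5 or dKO 6). Acaca rose by 1.09 ± 0.0527, Scd1 by 0.81 ± 0.0433 and Acly by 0.48 ± 0.0403. In WT they stood at 215.8 to 244.4, 3428 to 4069 and 405.8 to 448.8 CPM. Their tKO levels were 221.6 to 250.8, 3477 to 3786 and 384.5 to 391.9, while dKO levels lay below both. Of 29 interferon genes 15 rose and 1 fell (camera adjusted p = 0.000429; adjusted p = 0.274 with an estimated correlation), with Mx1 at 1.02 ± 0.142. Sphingolipid synthesis genes numbered 8 higher and 1 lower of 17 (camera adjusted p = 0.099), with B4galt5 at 0.39 ± 0.0556. Other genes that rose were the splicing factor Mbnl2 (2.37 ± 0.0614), Cyp2a5 (2.07 ± 0.0342, from 1881 to 7880 CPM), the heat shock protein Hspb1 (1.78 ± 0.0587), Derl3 (1.60 ± 0.127), Tubb2b (1.59 ± 0.156) and Txnip (1.57 ± 0.0677). Other genes that fell were Cyp2a22 (−2.78 ± 0.0954), Erdr1 (−2.75 ± 0.0702), Ddit4 (−2.11 ± 0.068) and the steroid hydroxylase Cyp17a1 (−2.01 ± 0.124). Cyp2a4, Cyp2a5 and Cyp2a22 belong to a family of similar sequence that was not summed, so their single values are uncertain.

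**Figure D3:**
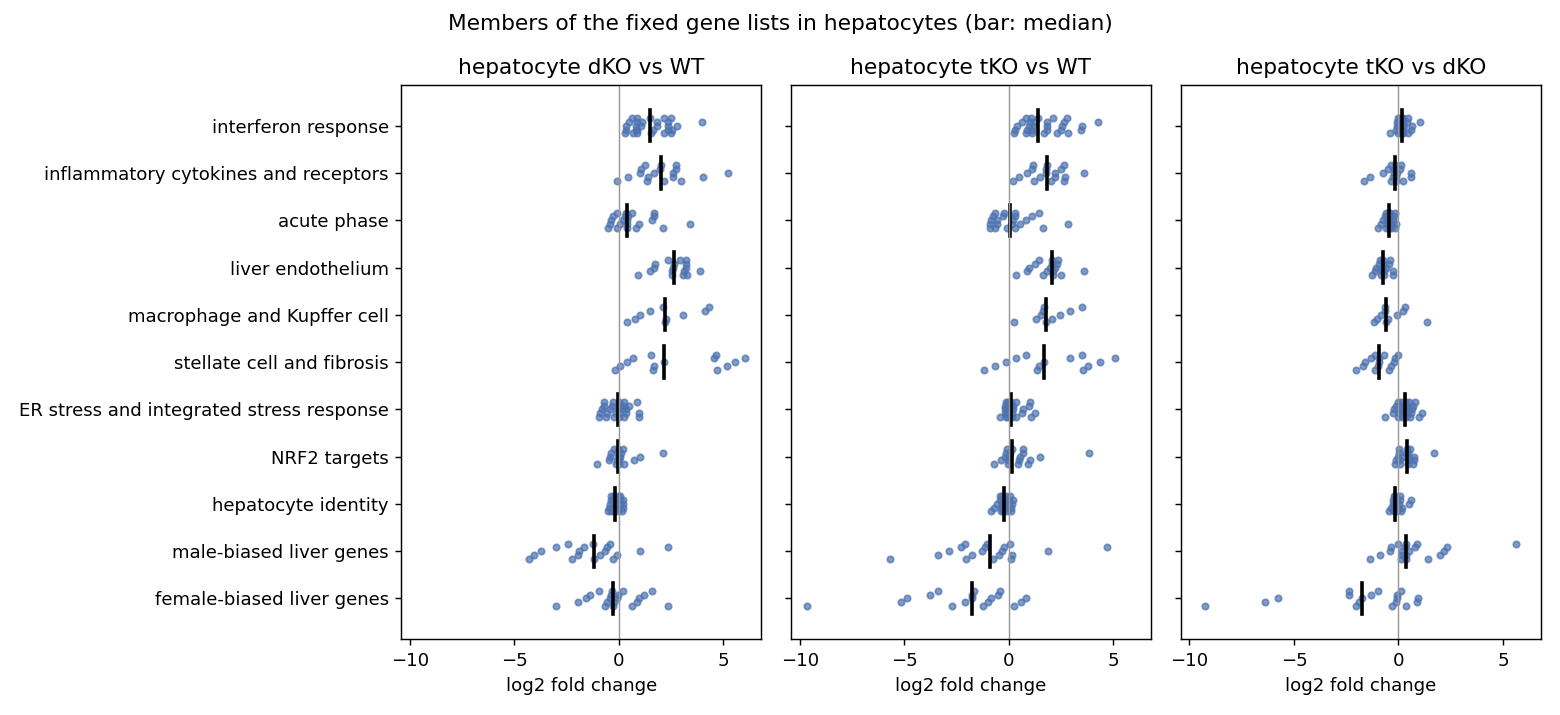
Each point is the log2 fold change of 1 member of a fixed gene list in a hepatocyte contrast, and black bars give list medians, with members not listed in a whole group kept in the medians but not drawn. The interferon median lies at 1.5 in dKO and 1.42 in tKO against WT, and the female-biased median at −1.77 in tKO against WT.

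Between tKO and dKO edgeR called 3382 of 11471 genes, 1641 higher and 1741 lower, and 312 changed at least 2-fold. With the liver dispersion 326 were called, including 12 female-biased genes lower, while 2 of the 22 acute phase genes, 3 of the stress response genes and 1 of the NRF2 targets were called. Of the endothelial genes 5 lower were called, of stellate cell genes 5 lower, of male-biased genes 6 higher and 1 lower, of de novo lipogenesis 2 and 0, of interferon genes 1 and 0, and of sphingolipid synthesis 0 and 0. The share of calls that were higher, 48.5%, was 33.7% with that dispersion, 56.4% with scaling by library totals alone and 58.2% with limma on log2 FPKM plus 1. The calls of Hspa5, Hsp90b1, Saa2, Steap4, Gsta2, Acly and B4galt5 ended with the liver dispersion. camera called 13 of 34 lists, 6 of them with an estimated correlation.

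**Figure D4:**
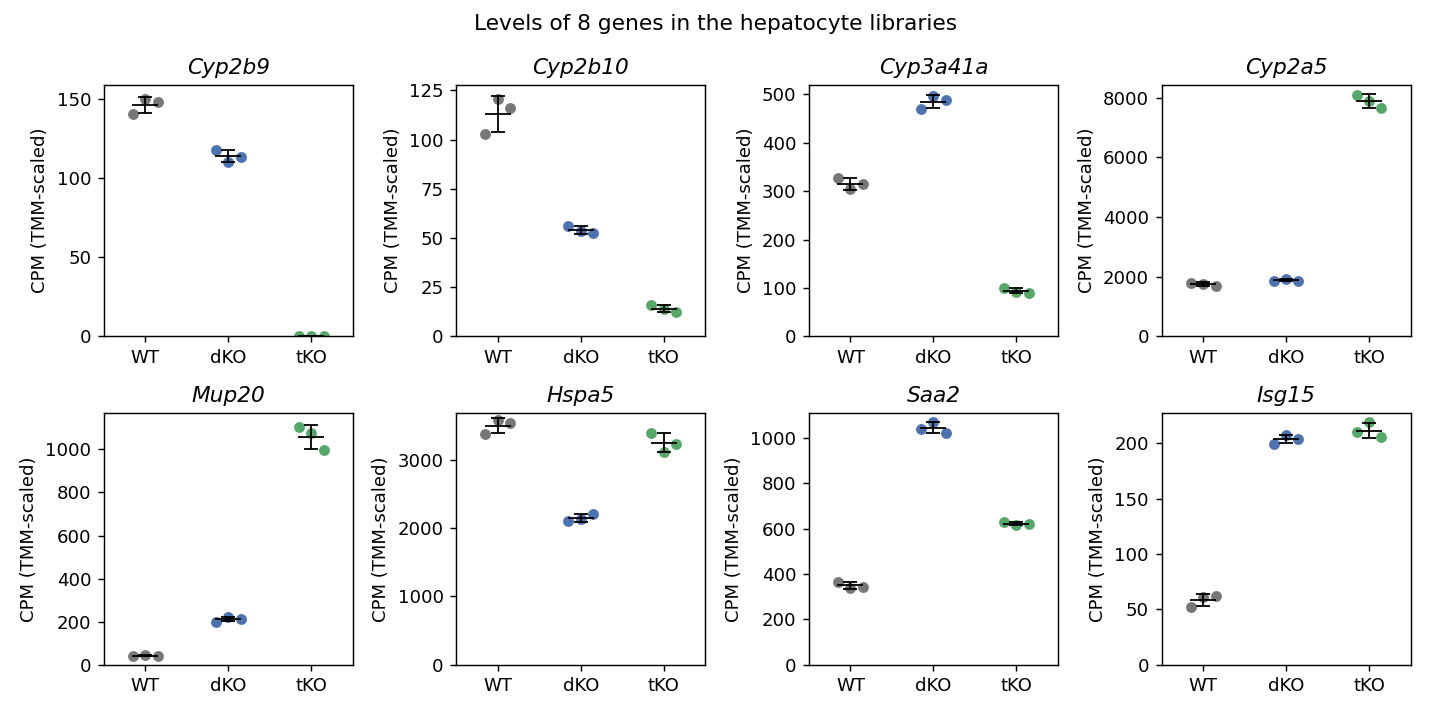
Points give the TMM-scaled CPM of 8 genes in each hepatocyte library, and bars the mean and SD of the group (n = 3). Cyp2b9 averages 146, 114 and 0.171 CPM in WT, dKO and tKO, and Cyp2a5 averages 7880 in tKO, an uncertain value in a family of similar sequence.

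Libraries labelled dKO and libraries labelled tKO were compared with the same WT libraries. 3452 genes were called in both in the same direction, 2009 higher and 1443 lower, and 186 in opposite directions. Independent lists of these sizes would share 1204 in the same direction. In 20 simulations of unchanged groups against the same WT libraries the median was 0 and the highest 1. Few calls arise where no gene changes, so this count does not show how far shared WT libraries raise an overlap of real calls. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.826, against 0.51 in the simulations. Their covariance was 0.465 against a simulated 0.013, a difference of 0.452. The 3 WT libraries could not be split into sets of 2 or more, so part of the excess may come from them.

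Whether SMSr loss moved the same genes in liver and in hepatocytes was asked over 11148 genes tested in both. Log2 fold changes of SMSrKO against WT liver and of tKO against dKO hepatocytes correlated with Pearson's r of −0.023 and Spearman's rho of −0.094 across genes. Leaving out single libraries gave r from −0.028 to 0.033, positive without WT 1, 2, 3 or 4 or SMSrKO 7 of liver. Of 23 genes called in liver and 3290 in hepatocytes, 7 were shared, all in the same direction, against 3.42 in the same and 3.37 in opposite directions for independent lists. Named after their values were seen, Phyhip, Krt5 and Slc35d2 were higher in both, by 3.72 ± 0.471, 1.48 ± 0.196 and 0.58 ± 0.0985 log2 in hepatocytes. Fabp4, Aen, Arhgap10 and Adcy1 were lower in both, at −0.36 ± 0.138, −0.19 ± 0.0598, −0.69 ± 0.26 and −0.30 ± 0.105. The hepatocyte calls of these 4 were each lost without at least 1 single library, at edgeR adjusted p of up to 0.29, 0.109, 0.143 and 0.162. Lists, compared after their values were seen, went both ways. At an unadjusted p under 0.05 in edgeR, NRF2 targets numbered 0 higher and 4 lower in liver, against 12 and 2 in hepatocytes. Female-biased genes numbered 6 and 0 against 3 and 13, and stress response genes 1 and 7 against 17 and 4. Acute phase genes went the same way, 0 and 6 against 0 and 22. With an estimated correlation camera called 0 liver lists.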

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

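The splits of the libraries and the tests near the targeted genes were written before their results were seen. The tests of marker genes, sex, shared reads and neighbouring genes were chosen after the results were seen, and the separate test of the Cyp2b family was added after the sums of the families were seen. After their first values were seen, the readings of 3 tests were moved to open, the neighbour test from argued against and the marker median and parent gene tests from in favour. The grouping of the samples follows labels that the targeted genes did not check.

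In hepatocytes labelled dKO, endothelial, macrophage and stellate markers stood higher than in WT, with medians of 2.65, 2.23 and 2.14 log2, the last 2.13 to 3.37 without single libraries. More non-parenchymal cells in the dKO and tKO isolates stay open as an explanation. A distance of 0.504 between the medians decides little where single members spread by an interquartile range of 1.87. The 7 cholangiocyte genes went both ways in dKO, 2 higher and 3 lower at an unadjusted p under 0.05 in edgeR. Their median was −0.11, which decides little too. Summed acute phase genes gained 5990 CPM in dKO and the summed markers 1040, a ratio of at least 4.26 in every pairing of a dKO with a WT library, which leaves open whether such cells or their signals could raise acute phase genes. In tKO the summed markers stood at 1697 to 1772 CPM against 952 to 1006 in WT. The summed acute phase genes stood at 33000 to 33880 against 35530 to 37750. Their members went both ways, 11 higher and 10 lower of 22 at an unadjusted p under 0.05 in edgeR. Fga stood at 3148 to 3315 CPM in tKO against 5767 to 6055 in WT, and Saa1 at 1061 to 1121 against 474.5 to 554.8. The sum follows abundant members such as Fga, so it does not tell whether acute phase genes rose with the markers there. The labels name no sort that would remove such cells, and genotype stays open as an untested explanation.

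In hepatocytes labelled tKO, female-biased genes stood lower than in both other groups, with Cyp2b9 at 0.171 CPM. That the tKO mice were male is argued against by the male-biased median of −0.89 against WT and by Ddx3y, on the Y chromosome, which was not listed in tKO libraries, although 10 male-biased genes were higher in tKO than in dKO. Ddx3y was not listed in dKO libraries either and had 1 count in WT 2, so it showed no difference in sex between the groups. Reads shared between near-identical copies are argued against for Cyp2b9 and Cyp2b13, since the summed Cyp2b family was at least 13 times higher in every dKO than in every tKO library. For the other members they stay open, since 1 of 3 families fell by over 1.5 times as a sum, and the Cyp3a sum was 0.714 to 0.82 times as high in dKO as in tKO. Genotype stays open, untested.

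Among the 37 liver calls were 5 pseudogenes and 7 genes on chromosome 15 (Fisher's exact p = 0.000429, chosen after it was seen and unadjusted). Donor-strain sequence near Samd8 is argued against, since 0 calls lay within 10 Mb of it. Segments of another strain elsewhere could not be told apart from chance, with 9 calls having another within 5 Mb against a median of 6 in 10000 random draws (permutation p = 0.26). Reads shared with the parent gene stay open: both parents of 2, Rpl3 and Rpl15, moved against their copies by more than their SD, which shared reads would need, but at adjusted p of 0.445 and 0.377 in edgeR. Genotype stays open, untested.

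Chance was tested for each count of calls. In liver 1 of the 35 splits of the libraries, the real one with 37 calls, gave a count that large, and the highest other gave 3. This share of 0.029 is the lowest that 35 splits can give, so it argues against chance but does not exclude it. It takes the libraries as separate animals, which the labels do not say, and cannot tell genotype from any other difference between the groups. In hepatocytes the 10 splits of each pair of groups are too few for a share under 0.05, and the real ones gave 5166, 5307 and 3223 calls against at most 0, 0 and 3 in the others, for dKO against WT, tKO against WT and tKO against dKO. Within 10 Mb of the targeted genes lay 2.04% of the calls of dKO against WT and 0.74% of those of tKO against dKO. Those ranges held 168 and 98 tested genes, against 5045 and 3382 calls. Most calls could not lie there whatever the cause, so these shares decide nothing. Donor-strain sequence stays open for the genes in those ranges. Near Sgms1 and Sgms2 61.3% of genes were called in dKO against WT and 43.7% elsewhere (Fisher's exact p = 6.73e-06). Near Samd8 25.5% were called in tKO against dKO and 29.5% elsewhere (Fisher's exact p = 0.437).

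Single liver libraries lay far from the 3 others of their group in 15 of 122 groups of values tested, 7 of them in WT 1, where chance gives about 1 in 20. In WT 1, Tle1 stood at 48.43 CPM against 50.46 to 50.73. The list sums below are relative to library totals without TMM scaling, which shifts single libraries. Alb in WT 2 stood at 38260 CPM by library total and at 35390 CPM with TMM. The flags of list sums were not tried with TMM scaling and may depend on it. Fatty acid uptake genes summed to 3752 CPM in WT 1 against 7053 to 7552. Bile acid genes summed to 5410 in WT 1 against 6470 to 6500. Glucose, fructose and insulin genes summed to 16110 in WT 1 against 11410 to 12060. Acute phase genes summed to 54610 in WT 1 against 22210 to 27080. Pericentral genes summed to 10510 in WT 1 against 17060 to 17460. NRF2 targets summed to 2030 in WT 1 against 2948 to 3120. In SMSrKO 6, Slc35d2 stood at 56.51 CPM against 37.88 to 39.81. In SMSrKO 7, Fam13a stood at 66.75 CPM against 53.88 to 54.95, cell cycle genes at 156.3 against 141.6 to 143.7, and female-biased genes at 10700 against 7620 to 8074. In SMSrKO 8, sphingolipid breakdown genes summed to 741.9 CPM against 627.3 to 639.8, lipoprotein genes to 52880 against 54340 to 54520, T, NK and B cell genes to 80.96 against 36.65 to 42.8, and neutrophil genes to 63.91 against 8.05 to 12.1.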

How the results depend on the processing

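The fold minimum of 2 and the liver dispersion in the hepatocyte fit were chosen after the data were seen, and the others before. No paired analysis was possible because the groups compared share no replicate numbers (1 to 4 and 5 to 8 in liver, 1 to 3, 4 to 6 and 7 to 9 in hepatocytes). Of 295 values under alternatives of the counts of calls, overlaps, list counts and targeted genes in the comparisons of their own lesion, 258 kept direction, side of the threshold or a count within 1.5 times, 27 moved, 5 lost the call and 5 reversed. The 37 liver calls became 136 with no filter beyond 1 count, 23 at a mean of at least 1 CPM, 451 with DESeq2, 22 and 20 with limma on log2 TPM plus 1 and 0.1, and 21 at 2-fold or more. All 37 remained without the filter and with DESeq2, 23 with the CPM minimum, and 17 and 16 with TPM. Leaving out single libraries gave 11 to 109 liver calls, 109 without WT 1, 23 without WT 3, 11 without WT 4, 13 without SMSrKO 5 and 15 without SMSrKO 7. The hepatocyte counts of 5045, 5435 and 3382 became 1055, 1221 and 326 with the liver dispersion, of which 1049, 1205 and 316 were among the former, 849, 897 and 312 at 2-fold or more, and 4517 to 5265, 4872 to 5488 and 2825 to 3356 without single libraries. Calls shared by dKO and tKO against WT fell from 3452 to 765 with the liver dispersion and to 3059 to 3386 without single libraries. With that dispersion 7 calls of targeted genes ended, 5 of them among the 295 values, while their folds stayed: Samd8 and Sgms2 in dKO 0.228 and −0.287 (adjusted p = 0.865 and 0.759 in edgeR), Samd8, Sgms1 and Sgms2 in tKO against WT 0.53, 0.239 and −0.291 (0.189, 0.778 and 0.671), and Samd8 and Sgms1 in tKO against dKO 0.302 and −0.624 (1 and 0.207). The calls of 18 other named genes ended with it at adjusted p of 0.0591 to 1: Cyp3a41a, Hmgcs1, Mdm2 and Sptlc2 in dKO against WT, Alb and Hexa in tKO against WT, and Acly, Adcy1, Aen, Arhgap10, B4galt5, Fabp4, Gsta2, Hsp90b1, Hspa5, Saa2, Slc35d2 and Steap4 in tKO against dKO. The setting assumes a larger spread, so such calls end by construction. Its single dispersion for all genes and its likelihood ratio test were not tried apart. The correlation of liver and hepatocyte fold changes, −0.023, was −0.06 over genes of at least 5 CPM, −0.028 to 0.033 without single libraries, and reversed without liver WT 1 (0.032), WT 2 (0.026), WT 3 (0.015), WT 4 (0.033) and SMSrKO 7 (0.024). camera called 24, 16, 12 and 13 lists for SMSrKO, dKO against WT, tKO against WT and tKO against dKO, against 0, 8, 7 and 6 with an estimated correlation and 1, 29, 30 and 25 with fry. Of 1492 list values 1320 kept direction and side of the threshold, 110 lost and 62 gained a call. Apart from the dispersion, the cause was not tested. The liver self-test recovered 17.9% of 1.5-fold changes, so smaller liver changes may be missed. In edgeR 2075 genes had an unadjusted p under 0.05, and DESeq2 called 451. Whether these counts reflect missed changes was not tested.

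Of 3193 values of single genes under alternatives 3000 kept their side of the threshold, 181 lost and 12 gained a call, and 0 reversed. Among 23 named liver calls 18 were lost without at least 1 library: 1 without WT 1, 10 without WT 2, 15 without WT 3, 17 without WT 4, 17 without SMSrKO 5, 10 without SMSrKO 6, 17 without SMSrKO 7 and 6 without SMSrKO 8. Agxt stood at 1.01 to 1.16 log2 without the 6 libraries that ended its call, and Smpd3 at −1.52 and −1.43 without SMSrKO 5 and 7. In tKO against dKO, Adcy1 lost its call without dKO 4, dKO 5, tKO 7 or tKO 9 (−0.29 to −0.22), Aen without dKO 4 or tKO 8 (−0.14 and −0.16), Arhgap10 without dKO 5, dKO 6, tKO 7 or tKO 8 (−0.64 to −0.59) and Fabp4 without dKO 5, dKO 6, tKO 7 or tKO 9 (−0.36 to −0.23). Folds of called genes with few counts in 1 group moved by over 1.5 times: Grem1 to 10.68 without liver WT 4, Phyhip to 7.07 without liver WT 2 and to 4.64 without dKO 6, Cybb to 6.23 and Duoxa2 to 5.79 without hepatocyte WT 1, and Mmp3 to 7.39 and Krt23 to 5.62 without hepatocyte WT 3, the last 4 in dKO against WT. In tKO against WT, Cybb moved to 6.77 and Duoxa2 to 5.73 without hepatocyte WT 1, and Krt23 to 5.52 without hepatocyte WT 3.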

Other observations

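The tests of Rpl34 and of shared directions were chosen after the result was seen, and the test on chromosome 14 before, although its reading and that of shared directions were moved from argued against to open after their values were seen.

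In hepatocytes labelled dKO, targets of p53 rose, 11 of 19 with 2 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.00745; adjusted p = 0.11 with an estimated correlation), among them Gadd45b (1.28 ± 0.0735) and Mdm2 (0.59 ± 0.0456). Bile acid genes went both ways, 7 higher and 9 lower of 20 (camera adjusted p = 0.000219; adjusted p = 0.146 with an estimated correlation), with the transporters Slco1a1 (−1.93 ± 0.0894) and Abcb11 (−0.76 ± 0.0585) and the hydroxylase Cyp27a1 (−0.84 ± 0.0453) lower. Of 24 cholesterol synthesis genes 15 rose and 2 fell (camera adjusted p = 0.0534, and 0.0417 to 0.0478 without WT 3, dKO 4 or tKO 7), with Hmgcs1 at 0.40 ± 0.0405. With the liver dispersion 1 and 0 of these were called, of p53 targets 3 and 0, of bile acid genes 1 and 6, of female-biased genes 5 and 5 and of cholangiocyte genes 2 and 0. Female-biased genes numbered 7 higher and 10 lower of 21 (camera adjusted p = 0.000406; adjusted p = 0.128 with an estimated correlation), with Cyp2c69 at −1.56 ± 0.0423 and Cyp3a41a at 0.62 ± 0.0404. The pyruvate dehydrogenase kinase Pdk4 rose by 1.89 ± 0.0527 in dKO and 1.81 ± 0.0528 in tKO against WT. Of 7 cholangiocyte genes 2 rose and 2 fell over all genes, and 2 and 3 adjusted over the list alone, with a median of −0.11 against the upward direction of camera (adjusted p = 0.0451; adjusted p = 0.178 with an estimated correlation).

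In hepatocytes labelled tKO, sphingolipid breakdown genes numbered 8 higher and 3 lower of 20 against WT (camera adjusted p = 0.423), with the lysosomal enzymes Asah1 (0.83 ± 0.06) and Hexa (0.63 ± 0.0632) higher. The bile acid hydroxylase Cyp8b1 fell by 2.46 ± 0.184. NRF2 targets numbered 10 higher and 4 lower of 19 (camera adjusted p = 0.000186; adjusted p = 0.143 with an estimated correlation), and stress response genes 13 higher and 6 lower of 27 (camera adjusted p = 0.0365; adjusted p = 0.198 with an estimated correlation), with Asns (1.04 ± 0.0606), Ddit3 (1.28 ± 0.0841) and Atf3 (1.05 ± 0.0559) higher. With the liver dispersion 2 higher and 0 lower sphingolipid breakdown genes were called, 5 and 1 NRF2 targets, and 4 and 0 stress response genes. The camera call of the stress response genes was lost without WT 1 or tKO 8, and that of the cholangiocyte genes in dKO without WT 2, dKO 4, dKO 6, tKO 7 or tKO 9. In liver, 24 cholesterol synthesis genes had a median of −0.58 (−0.22 without WT 1) and 11 neutrophil genes of −1.15 (−0.52 without WT 1 and −2.96 without SMSrKO 8), with 0 passing edgeR over all genes or adjusted over the list alone, and 9 and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 5.98e-05 and 0.000138; adjusted p = 0.416 and 0.415 with an estimated correlation).

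In hepatocytes Rpl34 fell by 4.67 log2 in dKO while its processed copy Rpl34-ps1 rose by 5.75. Their summed CPM changed by at most 0.42 log2 against WT, as reads shared between near-identical copies would allow, a hypothesis found on the same data. Shared reads alone would act alike in every library, so what made the groups differ stays open, untested.

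Phyhip, on chromosome 14 with Samd8, was higher in liver SMSrKO than WT and in hepatocyte tKO than dKO. Donor-strain sequence on chromosome 14 could not be told apart from other explanations. Of its tested genes 2.36% were called at 2-fold or more in tKO against dKO and 2.73% of those elsewhere (Fisher's exact p = 0.872), a difference within its error. The 7 genes called in both comparisons moved in the same direction (exact two-sided sign test p = 0.0156). Chance stays open, since the test was chosen for directions already seen and the genes are not independent replicates, and 4 of them lost their hepatocyte call without at least 1 library.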
